A study of Mus musculus with 6 samples.

How the data were processed

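Whole mouse embryos at the blastocyst stage (E3.5) were compared by sex on 2-colour Agilent oligonucleotide arrays. Per the labels' protocols, B6C3F1 females of 8 weeks received 5 IU each of 2 hormones that induce ovulation, pregnant mare serum gonadotropin and, 48 h later, human chorionic gonadotropin, and were mated with XGFPY males. Embryos of 4 cells were taken from the oviducts 55 h after the second hormone and cultured for 38 h in kSOM, an embryo culture medium, at 37 °C under 5% CO2. Per the labels, RNA was taken with ISOGEN from pools of over 200 embryos of a single sex with 1 µg of yeast tRNA as carrier, and was amplified linearly and labelled with an Agilent low-input kit. Per the series' design text, 3 independent preparations were made and each was hybridised in both dye orientations, which gives 6 arrays.

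Scans were read with Feature Extraction version 7.5 and arrays were combined with Luminator, per the series' design text; whether the deposited value table comes from the former or the latter is not given in the sources used here. The authors deposited 1 log ratio per feature and array, with no missing value among 21446 features. Its base, direction and centring are not stated. The deposited values were taken as log10, because they stop at exactly -2 and 2, whole powers in that base. The upper limit was reached only on the preparation 1 array with female RNA in Cy5. These limits say nothing of direction, which was taken as Cy5 over Cy3. Read the other way, preparations 1 and 2 would go against their labels on Xist and Eif2s3y, and preparation 3 would not. Of all values, 2.11% are exact zeros. The values were multiplied by 3.32 to give log2 ratios. Every fold change given here depends on that reading of the base, while calls without a size limit do not. Array medians lay between 0 and 0.00223 on the deposited scale, and no further centring was applied. Signal intensities, spot flags and control spots were not analysed here, so dim or saturated spots could not be filtered and signal over background is unknown; the number of arrays limits the precision.

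Direction came from the dyes in the labels: arrays with female RNA in Cy5 were kept and those with female RNA in Cy3 were turned in sign. This departs from a rule fixed before the data were examined, which said that no array is turned if the orientations correlate above 0. They did (r from 0.523 to 0.893 over all rows and all pairs of arrays, across genes, which are not independent replicates), but Xist and Eif2s3y changed sign between the 2 orientations of every preparation, so the shared part was a dye effect of single probes and not a common direction. With no array turned, limma called 0 rows and 4952 had an unadjusted p under 0.05, which measures the dye effect and not sex.

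With ratios read as Cy5 over Cy3, the sex labels of the preparation labelled 3 are contradicted by Xist and Eif2s3y on both its arrays. The main test kept the labels. Leaving that preparation out was planned before the data were examined, as was leaving out each of the others. Turning the sign of its ratios ("preparation 3 turned") was added after those genes had been seen. Every test on sex-chromosome genes with this setting is therefore partly fixed by the choice. The p-values of such tests cannot be read as those of a planned test. In this setting the dye orientation of preparation 3 was exchanged too. Its array labelled with male RNA in Cy5 then counts among the arrays with female RNA in Cy5, and the reverse.

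Genes were named through the platform annotation supplied with the table, with symbols and chromosomes updated by gene number from the reference gene table of GRCm38.p6 (11782 of 11813 probes with a single symbol matched). Another 559 probes carried several symbols and 9074 were not listed; these were tested as unnamed rows. A gene was the mean of its single-symbol probes (2180 genes had several), which gave 18606 rows: 8973 genes and 9633 unnamed rows. Of the genes, 312 were X-linked, 2 Y-linked, 8630 autosomal and 29 without a chromosome. As the array names no genome build, no coordinates are given and only gene order was used.

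The 2 arrays of a preparation hold the same RNA extracts and were averaged to 1 replicate. The mean log2 ratio of the 3 preparations, female over male, was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. Gene lists (26 fixed before the data were examined, 22 with over 3 measured members) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests whether members move 1 way on balance or, in its mixed form, in either direction, without comparing them with other genes. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the 3 preparations, so its p can rise even where that correlation is small. Lists left out of the test for too few members were the Y-linked genes, the Rhox cluster, sperm and spermatids, and blood cells. Distance from Xist was counted in genes, with 100000 permutations. The preparation number pairs male and female RNA by construction, since both lie on the same array. Alternatives fitted all 6 arrays with the preparation as a replicate block (duplicateCorrelation, statmod 1.5.0), with and without a dye term. In every fit of 6 arrays, the X-linked genes and the lists were tested with cameraPR instead of camera. That form takes each row's estimate over its standard error as given, at the preset correlation. A call that changes there can come from the form of test as well as from the fit.

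Genes named in the text were chosen by a rule fixed beforehand: a set of sex-linked genes; up to 12 genes per direction past the threshold, or the 6 of smallest p where fewer passed, in both cases only among genes with 1 sign on all 6 arrays; and, from each list, up to 4 members past the threshold or the 2 of smallest p. The same rule was applied again with preparation 3 turned and to its 6-array fit. Tsix, Ddx3y, Uty, Zfy1 and G6pdx had no single-symbol probe and were not analysed here.

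The tests were tried, for the comparison with preparation 3 turned, on simulated data with the real rows and dye effects and 200 changed rows, in 5 draws for each of 2 noise models. The fit of 3 preparation means recovered 0.4% of changes of 0.5, 51.2% of changes of 1 and 92% of changes of 4 on the log2 scale when noise was shared by the arrays of a preparation, with 4.05% of its calls false. The 6-array fit with block and dye term had 5% false calls when noise was drawn per array at the observed block correlation of -0.15. That noise came from the fit's own variance prior, independently between rows, so a share near 5% was built in. The same holds for the 4.05%, with noise from the variance prior of the preparation means. It had 37.7% false calls when noise was shared within a preparation, which gave a mean block correlation of 0.12. The main test had been chosen without regard to these simulations.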

Results

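The study set gene expression in female blastocysts against that in male blastocysts, 3.5 days after conception. RNA from pools of over 200 embryos of each sex was hybridised together on 2-colour arrays, in 3 independent preparations and both dye orientations, so that each of the 6 arrays gives a ratio of female over male for 21446 features. The orientations form 2 groups of 3 arrays. Ratios below are log2, female over male, with the SD over preparations (n = 3) unless stated. They take the deposited values as log10 ratios of Cy5 over Cy3.

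Several genes of the sex chromosomes differed between female and male RNA in each preparation, with the opposite direction in the preparation labelled 3. Xist, the RNA that coats the inactive X chromosome, stood at 2.25 in preparation 1 and 2.09 in preparation 2, and at -1.55 in the preparation labelled 3. Eif2s3y, a Y-linked translation factor gene, stood at -1.75, -1.76 and 1.93 in the same order. Rhox5, an X-linked homeobox gene, stood at 1.30, 1.28 and -1.32, and Hprt, an X-linked purine salvage enzyme, at 0.68, 0.56 and -0.59. Each sign held in both dye orientations. The X-linked glycolytic enzyme Pgk1 (0.021, -0.14 and 0.083) lay near 0 in all preparations. So did the Y-linked Kdm5d (0.026, -0.13 and 0.069), measured by 1 probe. Although female embryos carry no Y, a ratio near 0 says nothing about the labels. Whether the gene was not expressed or its probe did not register it could not be told without signal intensities. Rhox5 and Hprt changed sign along with Xist and Eif2s3y, but their direction is itself under test here. The values of Xist and Eif2s3y check the labels, and the preparation labelled 3 goes against its own on both arrays. Any direction drawn from it below depends on that.

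**Figure D1:**
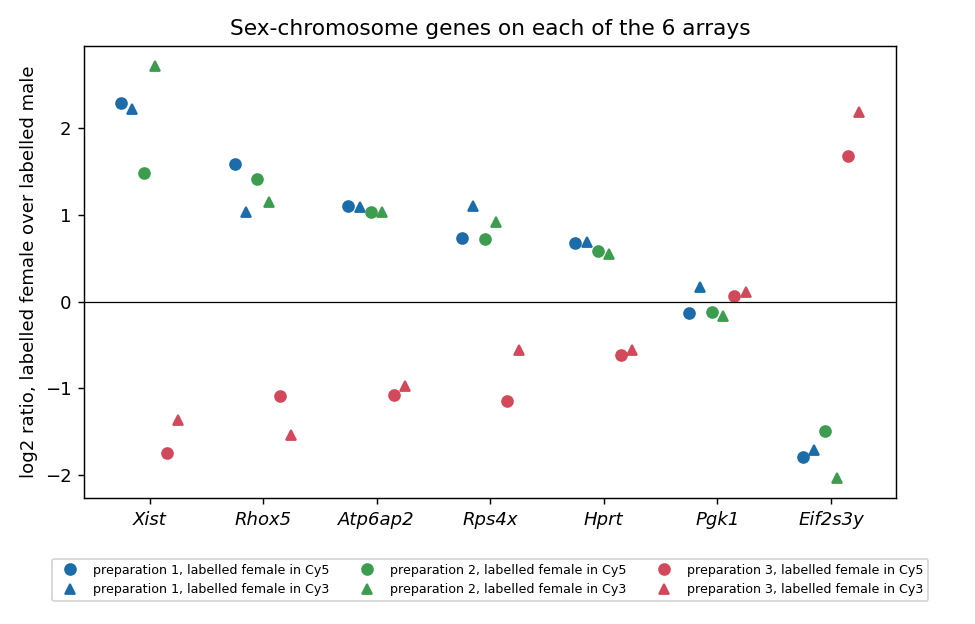
Log2 ratio of the RNA labelled female over that labelled male (vertical axis) for 7 genes (horizontal axis) on each of the 6 arrays; colours mark the preparation, circles arrays with female RNA in Cy5 and triangles those with female RNA in Cy3. Both arrays of the preparation labelled 3 lie on the other side of 0 from the other 4 arrays for Xist (-1.75 and -1.36) and for Eif2s3y (1.67 and 2.19).

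With all labels kept, no gene passed the test for a sex difference. limma called 0 of 18606 rows, and 484 rows had an unadjusted p under 0.05, where 930 are expected by chance. The gene with the smallest p was Traf6, a ubiquitin ligase of innate immune signalling, at -0.79 ± 0.026 with the same sign on all 6 arrays (limma adjusted p = 0.898). The arrays of preparation 1 differed, at -1.37 and -0.17, and in the labelled 6-array fit with block and dye term its limma adjusted p was 1. Among genes with 1 sign on all 6 arrays, the next male-higher genes by p, none past the test, were Rnf25 (-0.31), Pdk4 (-0.36), Tspyl2 (-0.24), Tfpt (-0.26) and Prkaa1 (-0.28); the female-higher ones were Cmss1 (0.30), Neil3 (0.26), Fbxl20 (0.30), Atg5 (0.16), Bcat2 (0.20) and Ap2s1 (0.16). The order and sizes of all these genes, Traf6 and its small SD included, rest on the labels of preparation 3. So does their shared sign, since turning that preparation leaves none of them with 1 sign on all 6 arrays. Tspyl2, for example, stood at -0.082 with that preparation turned. Without replicate 3 limma called 0 rows as well, with 838 at an unadjusted p under 0.05.

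With preparation 3 turned, a setting added after the sex genes had been seen, the X-linked female-higher genes named by the rule included Xist 1.97 ± 0.37, Rhox5 1.30 ± 0.020, Atp6ap2 1.05 ± 0.039, Nexmif 1.00 ± 0.15, Rbm3 0.88 ± 0.10, Rps4x 0.86 ± 0.049, Ssr4 0.81 ± 0.077 and Rpl10 0.79 ± 0.063. Rps4x and Rpl10 encode ribosomal proteins and Atp6ap2 an accessory subunit of the vacuolar proton pump. On the male-higher side stood Eif2s3y at -1.81 ± 0.10, then the autosomal genes Asrgl1 (-0.62 ± 0.10), Sike1 (-0.50 ± 0.069), Hexim1 (-0.45 ± 0.069), the metallothionein gene Mt1 (-0.42 ± 0.024) and Tubb2b (-0.36 ± 0.041). The 5 probes of Xist disagreed in size, with means from 0.44 to 4.33, all positive.

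The number of genes called with preparation 3 turned depended on the fit. The 3 preparation means gave 0 of 18606 rows (smallest limma adjusted p = 0.133; 1356 rows at an unadjusted p under 0.05). Restricted to named genes, limma called 3: Rhox5 (adjusted p = 0.0281), Eif2s3y (adjusted p = 0.0281) and Atp6ap2 (adjusted p = 0.0460). The 6 arrays with the preparation as replicate block and a dye term gave 39 rows, 36 female-higher and 3 male-higher. Of the 24 named female-higher genes in that fit 22 were X-linked (Fisher's exact test, two-sided, p = 1.08e-30), and the named male-higher genes were Eif2s3y and Mt1. The same arrays gave 139 rows with the block but no dye term and 14 with no block. None of these counts was planned. In simulations with noise shared within a preparation, 37.7% of the calls of the fit with block and dye term were false. Those simulations had a mean block correlation of 0.12, where the real fit had -0.15. Simulated noise per array, at a mean block correlation of -0.15, gave 5% false calls. That noise was drawn from the fit's own variance prior and correlation, so such a share was built in and does not bear on the 39 rows.

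X-linked genes as a group lay above autosomal genes in preparations 1 and 2, by a median difference of 0.11 and 0.058, and below them in the preparation labelled 3, by -0.088. As labelled the mean was 0.027 ± 0.10 and camera gave p = 0.0750 (p = 0.685 with an estimated correlation). Without replicate 3 it was 0.084 (camera on the limma fit across all genes, unadjusted p = 4.32e-11). Turning preparation 3 gave 0.086 ± 0.026, a 1.06-fold difference (camera p = 1.86e-13, but p = 0.0662 with an estimated correlation). With the mean in place of the median it was 0.15. In the arrays with female RNA in Cy5 alone, with the orientation of preparation 3 exchanged, it was 0.14. An exact sign-flip test over 3 preparations gave p = 0.25, the smallest it allows. No autosome's median moved by more than 0.015 in any preparation.

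**Figure D2:**
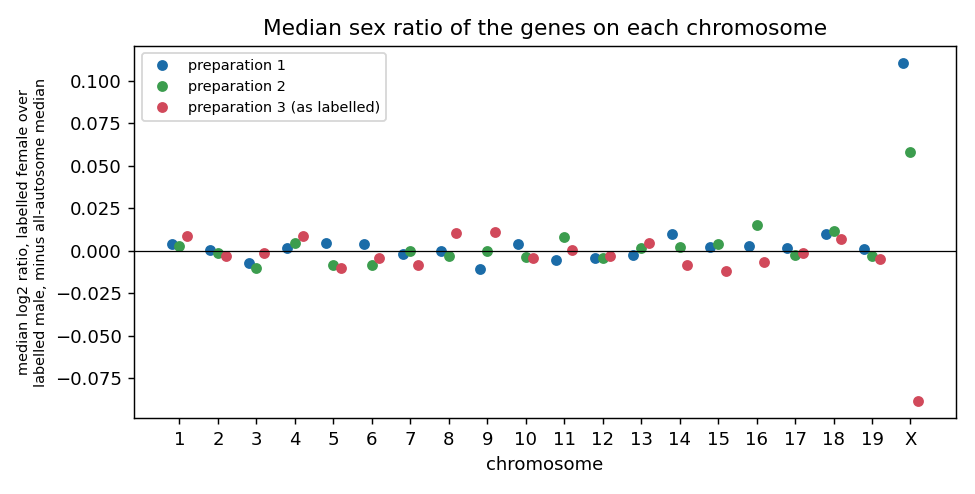
Median log2 ratio of RNA labelled female over RNA labelled male among the genes of each chromosome, minus the median of all autosomal genes (vertical axis), by chromosome (horizontal axis); points are the 3 preparations as labelled. The X chromosome lies at 0.11 and 0.058 in preparations 1 and 2 and at -0.088 in the preparation labelled 3.

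The shift was uneven among X-linked genes. As signal intensities were not analysed, genes not expressed in blastocysts could not be told from expressed genes without a sex difference. Counted with preparation 3 turned, 228 of 312 X-linked genes (73.1%) had a positive mean, against 51.7% of autosomal genes, and 43.3% were positive in all 3 preparations, against 18.4%. As labelled, 65.4% of X-linked genes had a positive mean, against 52.2% of autosomal genes, but 7.37% were positive in all 3 preparations, against 9.98%; 2 X-linked genes lay over 0.5 and 0 over 1. With preparation 3 turned again, 35 X-linked genes (11.2%) and 19 of 8630 autosomal genes (0.220%) lay over 0.5. Values over 1, a doubling, were reached there by 4 X-linked genes: Xist, Rhox5, Atp6ap2 and 1810030O07Rik, named after its value was seen. The X-linked genes had a median of 0.081, a lower quartile of -0.0082 and an upper quartile of 0.26.

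Among the lists of X-linked genes, housekeeping enzymes and regulators had a median of 0.36 with preparation 3 turned, and 22 of 25 members were positive. Examples are Hprt (0.61 ± 0.063), the pyruvate dehydrogenase subunit Pdha1 (0.61 ± 0.11), Rps4x and Ssr4. Genes known to escape X inactivation had a median of 0.42 (8 of 9 positive), with Utp14a at 0.42 ± 0.045 and the histone demethylase Kdm6a at 0.57 ± 0.22. All 5 measured genes with parent-of-origin expression were positive, led by Xist and Rhox5, with a median of 0.13. In the X-inactivation centre only Xist and Pbdc1 (0.68 ± 0.19) of 5 were positive, and the median (-0.12) and mean (0.36) differ in sign. Camera on the limma fit across all genes gave an adjusted p = 4.14e-15 for housekeeping genes, 4.56e-06 for escape genes, 7.56e-06 for parent-of-origin genes and 0.843 for the X-inactivation centre. With an estimated correlation the adjusted p = 0.410, 0.285, 0.285 and 0.884 in the same order. The correlations estimated were 0.25, -0.011, -0.23 and -0.24. In the 6-array fit with block and dye term, tested with cameraPR, the X-inactivation centre passed (adjusted p = 0.00123). Its median and mean were the same there, and both the fit and the form of test differed. As labelled, camera gave adjusted p = 0.539 for the housekeeping genes and 0.539 for the escape genes. Adjusted over the list alone, limma called 14 housekeeping and 5 escape genes with preparation 3 turned, against 0 over all rows. It called 3 genes of the X-inactivation centre on the same terms (Xist, Pbdc1 and Chic1, the last at -0.56), 2 with parent-of-origin expression (Rhox5 and Xist), 2 of trophectoderm (Krt7 and Lgals3), Ndufb11 of oxidative phosphorylation and Hspb1 of heat shock. The 5 escape genes were Xist, Pbdc1, Ddx3x, Kdm6a and Utp14a.

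Position relative to Xist was tested because inactivation spreads from that locus. As labelled, the ratio of X-linked genes did not follow the distance from Xist in gene order (Spearman's correlation = 0.089, permutation p = 0.117; r = 0.077, permutation p = 0.178; 312 genes, which are not independent replicates). Without replicate 3 it did (Spearman's correlation = 0.12, permutation p = 0.0359, not adjusted). Once preparation 3 was turned, Spearman's correlation was 0.13 (permutation p = 0.0210, adjusted p = 0.0419) and r was 0.11 (permutation p = 0.0547, adjusted p = 0.0729). Each coefficient was adjusted over its own 4 relations and not over both coefficients together. The adjusted p of 0.0419 therefore makes no allowance for having computed both. Without Xist and the 20 genes nearest to it, Spearman's correlation in that setting was 0.18 (permutation p = 0.00195, adjusted p = 0.00780) and r was 0.19 (adjusted p = 0.00380). As labelled, the same genes gave 0.11 (adjusted p = 0.0809) and r = 0.12 (adjusted p = 0.0729), all by permutation. With all genes and preparation 3 turned, Spearman's correlation was 0.074 without replicate 2 and 0.094 without genes of large dye effect, neither past the threshold.

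**Figure D3:**
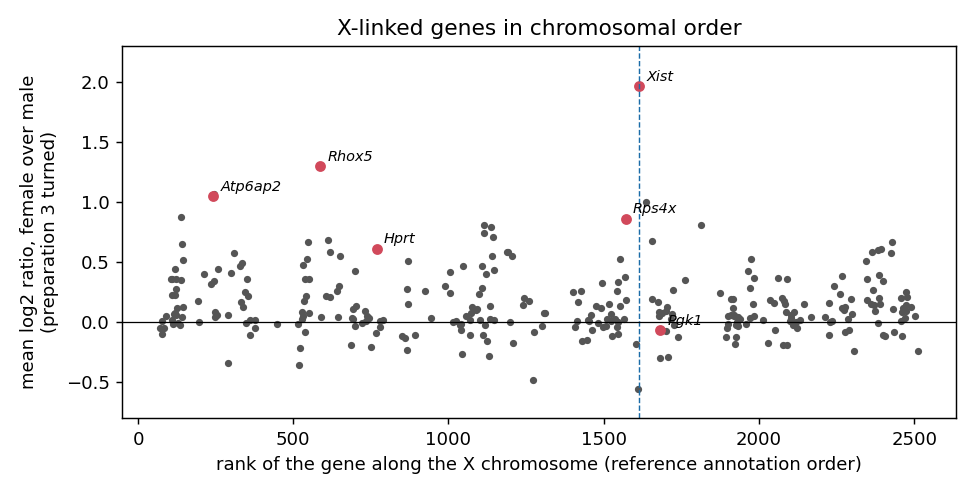
Mean log2 ratio of female over male with preparation 3 turned (vertical axis) for each measured X-linked gene, by its rank along the X chromosome in the reference annotation (horizontal axis); the dashed line marks Xist and red points are named genes. Points over 1 are few. Hprt (0.61) and Pgk1 (-0.069) belong to the housekeeping list, which runs from -0.27 (Hmgb3) to 0.86 (Rps4x).

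Pluripotency genes, which mark the inner cell mass, were slightly higher in the RNA labelled female in preparations 1 and 2, with list medians of 0.13 and 0.11, and lower in the preparation labelled 3, at -0.10. The pluripotency factors Nanog and Klf4 stood at 0.37 and 0.28 in preparation 1 and at 0.41 and 0.27 in preparation 2. Without replicate 3 the list's median was 0.13 with 17 of 20 members positive (camera adjusted p = 2.56e-05). Turning preparation 3 gave 0.12 with 18 of 20 positive (camera adjusted p = 1.26e-06, but adjusted p = 0.285 with an estimated correlation, and 0.211 in the arrays with female RNA in Cy5 alone). No member passed limma's test over all rows with the 3 preparation means, and 1, Nanog, passed adjusted over the list alone. As labelled the list was not past the threshold (camera adjusted p = 0.539).

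Heat shock and unfolded protein response genes had a median of 0.11 with preparation 3 turned, and 13 of 17 were positive, among them the chaperones Hspb1 (0.43 ± 0.068) and Hsph1 (0.28 ± 0.12). Camera gave an adjusted p = 0.00755, lost with an estimated correlation (adjusted p = 0.628). It was also lost without replicate 2 (median 0.11, adjusted p = 0.0506) and without replicate 3 (median 0.088, adjusted p = 0.0913). Without replicate 1 the list passed camera (median 0.079, adjusted p = 0.00376). In single dye orientations the call was lost as well (female in Cy5, median -0.0091, adjusted p = 0.761, and female in Cy3, median 0.21, adjusted p = 0.0641). Markers of other parts of the embryo did not pass camera's test: trophectoderm genes had a median of 0.012 (13 of 25 positive, camera adjusted p = 0.961), with Lgals3 at 0.52 ± 0.13 and Krt7 at -0.34 ± 0.045, and primitive endoderm genes one of 0.043 (12 of 17 positive, adjusted p = 0.417). Both passed fry's mixed test (adjusted p = 0.0302 and 0.0467), but the latter not without its 1 X-linked member, Cited1 (adjusted p = 0.406).

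Autosomal imprinted genes did not pass camera's test in either class. With preparation 3 turned, the maternally expressed genes had a median of -0.062 (5 of 17 positive, camera adjusted p = 0.267), with Nap1l4 at -0.28 ± 0.13, but passed fry's mixed test of change in either direction (adjusted p = 0.0109). The paternally expressed genes had a median of -0.0044 (5 of 13 positive, adjusted p = 0.919), with Nap1l5 at 0.31 ± 0.24. Lists for glycolysis (median -0.0093, adjusted p = 0.698), the pentose phosphate pathway and redox (-0.0075, 0.607), oxidative phosphorylation (0.025, 0.205), the cell cycle (-0.024, 0.613) and p53 and apoptosis (-0.080, 0.203) did not pass camera's test either. Nor did DNA methylation and Polycomb (0.050, adjusted p = 0.195), FGF and MAPK signalling (0.011, 0.919), interferon response (0.018, 0.554) and autosomal ribosomal proteins (0.044, 0.195). The mean differed in sign from the median for the paternally expressed genes (0.013) and for FGF and MAPK signalling (-0.0071). In the 6-array fit with block and dye term, oxidative phosphorylation passed cameraPR (adjusted p = 0.0260). It holds 2 X-linked members, Ndufb11 (0.49) among them, and without these the same fit gave a cameraPR adjusted p = 0.516. By fry on the 3 preparation means, 5 of 22 lists moved on balance 1 way with preparation 3 turned: the X-inactivation centre (adjusted p = 0.0281), parent-of-origin, housekeeping and escape genes, and pluripotency. Its mixed test passed 15 of 22 lists, and both forms passed 0 lists as labelled.

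Oocyte and maternal transcripts did not pass camera's test with preparation 3 turned (median 0.012, camera adjusted p = 0.793). Nor did genes of cells that could be carried along with embryos: cumulus and granulosa cells (0.017, 0.648) and oviduct epithelium (-0.038, 0.919). The oocyte list passed fry's mixed test (adjusted p = 0.0109). Of the lists too short to test, the single sperm gene, Oaz3, stood at -0.044 ± 0.32, and the blood cell gene Ptprc at -0.34 ± 0.091, with the other blood cell genes at -0.077 ± 0.17 (Lyz2) and 0.037 ± 0.027 (Fcer1g). The Y-linked list held only Eif2s3y and Kdm5d, and Rhox5 had the smallest p of the 3 measured genes of the Rhox cluster list.

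The dye effect, the technical background of these arrays, varied more across genes than the sex ratio did. Its SD across named genes was 0.27, against 0.14 for the sex ratio with preparation 3 turned, and 7.07% of named genes had a mean dye effect over 0.5. It was shared by the preparations (r = 0.432, 0.524 and 0.554 across named genes, which are not independent replicates). limma called 0 rows for it over 3 preparations, with 4952 at an unadjusted p under 0.05, and 446 with arrays centred on their median.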

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

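With labels kept, the count of called genes was 0 under all alternatives but the arrays with female RNA in Cy3 alone, which gave 628 (599 female-higher, 29 male-higher) and do not cancel the dye effect. With the replicate block and dye term the labelled count was 0; the pairing of both sexes on an array is part of every fit. The filter on missing values removed nothing. The X shift, 0.027 as labelled, passed the threshold at 0.038 with the replicate block without a dye term and at 0.038 without a block, at 0.029 without genes of large dye effect, at 0.027 with named genes only, at 0.084 without replicate 3 and at 0.086 with preparation 3 turned. It was 0.064 in female-in-Cy5 arrays alone, 0.012 in female-in-Cy3 arrays alone and 0.048 with the mean in place of the median, none past the threshold. Leaving out each preparation gave X shifts from -0.015 to 0.084, Spearman's correlation with distance from Xist from -0.047 to 0.12, and 0 to 4 lists past the threshold; the sign turned without replicate 1 for the shift and without replicate 2 for the correlation. With preparation 3 turned that correlation was 0.13 and 5 lists passed.

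With preparation 3 turned its dye orientation was exchanged as well, so single orientations there hold another array of it than with labels kept. Alternatives on top of preparation 3 turned were chosen after the data were seen. They gave 139 called rows with the block without dye term (50 X-linked female-higher), 39 with it (22), 14 without a block (8), 692 from female-in-Cy5 arrays alone (12; 85 female-higher and 607 male-higher in all), 3 among named genes (2) and 1 without genes of large dye effect, an unnamed feature. Spearman's correlation with distance from Xist was 0.089 and 0.060 in the single orientations and 0.094 without genes of large dye effect; leaving out preparations gave 0.074 to 0.16. The X shift lost its call with an estimated correlation, which leaves its value of 0.086 as it is by construction. It was 0.12 over 6 arrays (tested with cameraPR), 0.14 in female-in-Cy5 arrays alone and 0.093 in female-in-Cy3 arrays alone, all past the threshold. The mean in place of the median gave 0.15, which leaves camera's p as it is by construction. Of the 5 lists, 2 passed with female-in-Cy5 arrays alone and 0 with an estimated correlation. Without X- and Y-linked members 2 passed, pluripotency and heat shock. The housekeeping, escape and parent-of-origin lists hold only X-linked genes and could not be tested that way. With the replicate block, with or without dye term, and without a block, 7 lists passed, adding the X-inactivation centre and oxidative phosphorylation. Those fits of 6 arrays were tested with cameraPR, so the form of test differed as well as the fit. With block and dye term but without X- and Y-linked members 2 passed, again pluripotency and heat shock. Female-in-Cy3 arrays gave 4, among them DNA methylation and Polycomb. Single probes gave 7 and leaving out genes of large dye effect 6, both adding autosomal ribosomal proteins. The dye effect gave 446 rows centred, 797 scaled and 642 with exact zeros missing. In the block fits, the correlation fitted within a preparation was negative: -0.55 without a dye term and -0.15 with it. A negative value narrows the standard error of a mean, and it is all that separates the 139 rows from the 14. The causes of the other differences were not tested, beyond the dye effect left in by construction. Of 1688 values of named genes with preparation 3 turned, 84 had the other sign. Signal over background is unknown.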

Other observations

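Tests of the dye effect as a source of the autosomal correlation and of the pluripotency values were set before their results were seen; the tests on the labels of preparation 3, on a common autosomal difference, on trophectoderm genes and on sign patterns were chosen after.

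With preparation 3 turned, the 25 measured X-linked housekeeping genes had a median of 0.36 and the other 287 X-linked genes one of 0.068. Whether fewer of the latter were expressed could not be told without signal intensities. As labelled the list's median was 0.12, from 0.32 in preparation 1, 0.37 in preparation 2 and -0.36 in the preparation labelled 3, and that of all X-linked genes was 0.035. The autosomal gene Nanog (0.39 ± 0.018) had the smallest SD of the genes named by the rule in this setting (limma adjusted p = 0.536 over all rows, and 0.0393 in the 6-array fit with block and dye term). An unnamed probe, feature 5321, singled out after its values were seen, had the smallest adjusted p with preparation 3 turned (limma, 0.133), at -3.33 in preparation 1, -3.22 in preparation 2 and 3.49 in the preparation labelled 3, the same pattern as Eif2s3y. Traf6 had values of -0.77, -0.80 and -0.82 as labelled; it was picked for its smallest p with the labels kept, so its likeness between preparations says nothing about them.

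The opposite sign of preparation 3 may come from an exchange of female and male in its RNA or in both its array records. Across 311 X-linked genes other than Xist, its labelled ratios correlated at r = -0.583 with the mean of the others. An inverted ratio in the deposited columns is argued against by its dye effect, which ran with that of the others (r = 0.638). A sex difference that was itself reversed is argued against by the Y-linked Eif2s3y, at 1.67 or above in the RNA labelled female on both arrays. Where the exchange would have happened stays open, and the labels were not changed.

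Autosomal ratios of preparations 1 and 3, the latter turned, correlated at r = 0.312 over 8630 genes, while preparation 2 followed neither. They hardly followed the dye effect measured in preparation 2 (r = -0.027 and -0.093), and regressing it out left r = 0.310, which argues against a leftover dye effect shared with preparation 2. A dye effect particular to preparations 1 and 3 was not tested. The correlations of preparation 2, the lower at r = -0.0859, are part of this pattern and no separate test. They give no positive values for a sex difference common to all 3 across autosomal genes at large. A common difference in a few autosomal genes need not show in them. What preparations 1 and 3 share, such as handling or embryo stage, could not be tested with the labels given.

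The pluripotency list was higher in RNA from females with preparation 3 turned (median 0.12). A leftover dye effect is argued against, since the list's median was above 0 in both orientations (0.15 ± 0.042 and 0.081 ± 0.042, SD, n = 3 arrays). A larger share of inner cells cannot be told apart from a change within them: the trophectoderm median of 0.0083 ± 0.016 lay within its spread of 0, and the fall that such a share needs is not known. The list's call ended in the camera test with an estimated correlation. That correlation was -0.020, below the preset 0.01, so correlation among members does not account for the loss. This form of camera rests on the 2 residual degrees of freedom of 3 preparations. Chance stays open, as does a difference between the sexes, which may be offered only as a hypothesis.

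The 3 preparations allow only 4 sign patterns, too few for a share under 0.05. A real count of 0 is reached by all 4 patterns by construction and decides nothing; this holds for genes as labelled and with preparation 3 turned and for the dye effect (highest other count 0 each), and for lists as labelled (highest other count 5). In the 6-array fit with block and dye term, 1 pattern reached the 39 rows of preparation 3 turned, and the highest other count was 1. Rows at an unadjusted p under 0.05 numbered 1485 with preparation 1 turned instead, more than the 1356 with preparation 3 turned, against 484 as labelled and 387 with preparation 2 turned. For lists, 1 pattern reached the 5 of preparation 3 turned, with a highest other count of 0.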
